A study of Mus musculus with 6 samples.

How the data were processed

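The series holds 6 samples, 1 RNA library and 1 T cell receptor library from each of 3 groups: lymph node T cells of mice without a tumour, tumour T cells of mice without vaccination (Control) and tumour T cells of vaccinated mice (Vaccine). Per the labels, tumours were digested with collagenase and enriched for immune cells on a Percoll gradient, libraries were made with the 10x Genomics 5′ kit, and sequencing was done on a NovaSeq instrument. The submitters' processing notes name Cell Ranger, without a version, and the mm10 genome build. The deposited RNA matrices hold counts, that is UMIs per gene and barcode, and the deposited receptor contig tables hold counts of reads and UMIs per contig. The deposited clonotype tables hold counts of barcodes per clonotype and the fraction of barcodes that each clonotype makes up. No reference genome was used here, so no positions are given.

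The matrices had 31053 genes, 17109 of them with at least 1 UMI, and 20062 barcodes. Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Scrublet called 4 doublets in the naive lymph node library and 0 in the others, against expected rates of 4.18%, 5.60% and 6.26%, so doublet removal did not work and doublets remain among the 19322 kept cells. Median genes per kept cell were 1674, 1380 and 1718 in the naive lymph node, Control and Vaccine libraries, and the median ribosomal share of UMIs was 39.5%, 36.8% and 26.1%. All kept cells were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, without batch integration, since library and group coincide.

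The CD4 gate held cells with at least 1 Cd4 UMI and no Cd8a or Cd8b1 UMI, and the CD8 gate cells with at least 1 Cd8a or Cd8b1 UMI and no Cd4 UMI, among cells with a Cd3d, Cd3e or Cd3g UMI. UMIs were summed over the gated cells of a library and divided by all UMIs of those cells to give CPM, the UMIs of a gene scaled to the same total in every library. Log2 ratios carry exact conditional 95% intervals, shares carry exact Clopper-Pearson intervals and differences of shares carry Newcombe intervals. A count of 0 was set against a floor of 3 UMIs or cells. Marker shares were taken after thinning each cell to 1500 UMIs, which left out 20, 38 and 41 CD4 cells and 30, 114 and 172 CD8 cells of the naive lymph node, Control and Vaccine libraries.

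The 21 gene lists, the markers of 18 cell types, the comparisons and the rule for naming genes were fixed before the data were examined. For each list, members with at least 20 UMIs over the libraries compared gave a median log2 ratio, the number at least 1.5-fold higher or lower, and a percentile among 10000 random lists matched on expression in 20 bins. Genes were named as the 8 highest and 8 lowest log2 ratios per gate for Vaccine against Control, and the 6 highest and 6 lowest for Control against the naive lymph node, among genes with at least 50 CPM in 1 library and at least 50 UMIs in all. Receptor, immunoglobulin, haemoglobin, mitochondrial, ribosomal and unnamed genes were left out. Some genes that the rule picks are not reported here. For described lists, up to 3 members with the largest absolute log2 ratios were named. Expanded cells, in clonotypes of at least 5, were set against clonotypes of 1 cell within each tumour library and gate.

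Clonotypes were those deposited, for barcodes with a productive chain. Under these definitions a clone seen with its beta chain alone is listed apart from the same clone with both chains, so clone sizes are split. Clonality was the normalised Shannon index, and repertoires were rarefied by exact expectation.

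With 1 library per group no test of a group difference was possible, and CPM, list medians and shares describe these libraries. The procedures were tested on simulated data. In a simulated CD4 comparison of 8402 genes, 97% of 100 genes with a true 2-fold difference and 100% of those with a true 4-fold difference passed the 1.5-fold rule, as did 2.54% of unchanged genes, and 95.4% of intervals held the true value. In the CD8 simulation of 10522 genes these were 98%, 100%, 1.01% and 95.6%. Both simulations drew counts with Poisson counting error only, from 1 pooled profile, which is the model that the intervals assume. The coverage therefore checks the calculation. It does not show that the intervals or the 1.5-fold rule hold where UMIs cluster within cells or libraries differ for other reasons. Of 100 random lists without effect, 9 fell outside percentiles 5 to 95. Rarefaction gave 21.8% by expectation and 21.8% by drawing.

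Alternatives covered the filters, gates, thinning, scaling, list minimum, clonotype definition and clone size. Some choices were made after the data had been seen. The thinned share became an exact expectation in place of a random draw, the gate by cluster became a simple majority of gated cells, the lists described with members were picked after their medians were known, and the digestion stress test was relabelled as undecided after its value was known, because members of its list went both ways. Analyses used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 with its Scrublet function, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.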

Results

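The series profiled CD4 and CD8 T cells of C57BL/6 mice, an inbred laboratory strain, by droplet-based single-cell RNA sequencing and by sequencing of T cell receptor chains amplified from the same cDNA. Cells came from lymph nodes of mice without a tumour (the naive lymph node library), from tumours of mice that were not vaccinated (the Control library) and from tumours of vaccinated mice (the Vaccine library). The series title describes the treatment as a therapeutic vaccine, given as a prime and a boost and built on epitopes recognised by CD4 T cells. Each of the 3 groups had 1 RNA library and 1 receptor library. No difference between groups therefore had a replicate check, no test was run, and a difference between libraries cannot be assigned to the treatment. Ranges in brackets are 95% intervals that cover counting error only. Beside the median of a set of genes, the range runs between the medians of the members' lower and upper limits. Such a range does not cover the spread among members. The RNA libraries held 5226 barcodes and 27709451 UMIs for the naive lymph node, 7006 barcodes and 29102940 UMIs for Control, and 7830 barcodes and 37940945 UMIs for Vaccine. After filtering, 4986, 6787 and 7549 cells were kept, with medians of 5269.5, 3883 and 4614 UMIs per cell. The receptor libraries gave a productive chain in 4860, 5851 and 7011 cells.

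The kept cells were T cells: 98.9%, 95.6% and 98.8% of naive lymph node, Control and Vaccine cells held at least 3 of the 8 fixed T cell markers. Markers of other lineages were scarce. At least 3 B cell markers were found in 0.923%, 0.368% and 0.225% of cells, and at least 3 macrophage or monocyte markers in 0.160%, 0.103% and 0.212%. At least 3 dendritic cell markers, a set with Irf8 and Ccr9 that gated T cells also held (below), were found in 0.582%, 0.147% and 0.861%. For NK cell markers these shares were 0, 1.62% and 1.32%. Col1a1, the fibroblast collagen, had 4, 0 and 1 UMIs in the libraries, and Mlana, a melanocytic marker, had 0, 6 and 7. Genes of the NK cell marker set, which effector CD8 T cells also express, summed to 6.02 CPM (the UMIs of a gene scaled to the same total in every library) in the naive lymph node library, 735 CPM in Control and 543 CPM in Vaccine. Clustering of the 3 libraries together gave 19 clusters. The 10 leading genes of clusters 11 and 15 held 2 and 3 NK cell markers and no T, CD4 T or CD8 T cell marker, although 887 of 966 and 821 of 953 of their cells, each with a Cd3 and a Cd8 UMI, lay in the CD8 gate. Cluster 0, with 390 cells, was regulatory T-like, led by Tnfrsf4, Tnfrsf9, Ikzf2, Foxp3 and Il2ra. It held 131 naive lymph node, 188 Control and 71 Vaccine cells, of 4986, 6787 and 7549 kept. Several clusters consisted almost entirely of 1 library, among them cluster 6 (785 of 785 cells from Control), cluster 14 (1350 of 1372 from Control) and cluster 3 (1925 of 2006 from the naive lymph node). CD4 and CD8 cells were therefore separated by their own transcripts and not by cluster: the CD4 gate required a Cd4 UMI and no Cd8a or Cd8b1 UMI, and the CD8 gate the reverse.

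The tumour libraries held a larger share of CD8 cells than the naive lymph node, and the Vaccine and Control tumours had almost the same share. CD8 cells were 59.1% (57.4 to 60.7) of the 3524 gated naive lymph node cells, 81.9% (80.8 to 82.9) of 5263 Control cells and 82.1% (81.1 to 83.0) of 6540 Vaccine cells. Vaccine exceeded Control by 0.20 percentage points (-1.20 to 1.61), a difference not detectable at this depth, and Control exceeded the naive lymph node by 22.8 points (20.9 to 24.8). Cd4, the CD4 co-receptor gene, was sparsely captured. A Cd4 UMI was present in 56.7%, 47.2% and 65.2% of naive lymph node, Control and Vaccine cells in clusters with a CD4 majority, and in 4.08%, 4.38% and 4.52% of cells in clusters with a CD8 majority. These shares depended on the gate: assigning cells by their cluster's majority gave CD8 shares of 40.4%, 70.6% and 75.4%, so that Vaccine exceeded Control by 4.81 points and Control exceeded the naive lymph node by 30.2. Requiring at least 2 UMIs of the gate's own marker gave -2.56 and 15.1 points, and thinning every cell to 1500 or 1000 UMIs before gating gave 14.1 and 11.4 points for Control against the naive lymph node.

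The main comparison, Vaccine against Control tumours, asked how T cells in the tumours of vaccinated mice differed from those in unvaccinated mice. In the CD4 gate (1171 Vaccine and 953 Control cells), genes of type 1 helper cells, interferon response genes and the chemokine receptor genes Cxcr6 and Cxcr3 were higher in the Vaccine library, and genes of naive and central memory cells were far lower. Ifng (ENSMUSG00000055170), the main type 1 cytokine, stood at 262 CPM (248 to 276) in Vaccine and 90.1 CPM (80.7 to 100.3) in Control. Cxcr6 (ENSMUSG00000048521), a chemokine receptor of effector cells in tissues, stood at 468 CPM against 102 CPM. Foxp3 (ENSMUSG00000039521), the lineage factor of regulatory T cells, had fewer UMIs in Vaccine, at 6.32 CPM (4.38 to 8.83) against 16.1 CPM (12.3 to 20.8). These UMIs came from only 14 Vaccine and 30 Control cells. The share of cells with a UMI did not differ detectably after thinning (below).

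The 8 genes with the highest CD4 ratios, by a rule fixed in advance, were Ly6c2 at a log2 ratio of 2.34 (2.21 to 2.48), Cxcr6 at 2.19 (2.03 to 2.35), Plac8 at 2.17 (1.99 to 2.36), Ifitm3 at 2.16 (1.88 to 2.44), Krt83 at 2.05 (1.62 to 2.50), Cxcr3 at 2.00 (1.84 to 2.16), Lilr4b at 1.97 (1.59 to 2.36) and Il18r1 at 1.92 (1.69 to 2.15). Ly6c2 marks effector and memory T cells, Cxcr3 is the chemokine receptor that type 1 cells use to enter inflamed tissue, and Il18r1 is a receptor chain for interleukin-18. Among the 8 lowest were Igfbp4 at -8.29 (-9.35 to -7.40), Atp1b1 at -6.05 (-7.37 to -4.99), Ifngr2 at -4.51 (-5.40 to -3.73), Dapl1 at -3.92 (-4.40 to -3.48), Ramp1 at -3.81 (-4.46 to -3.21), Ly6c1 at -3.63 (-3.99 to -3.29) and Ccr7 at -2.92 (-3.11 to -2.74). Igfbp4 (ENSMUSG00000017493), a naive T cell gene, had 10 UMIs in Vaccine and 2157 in Control. Ccr7 (ENSMUSG00000037944), the receptor that guides T cells to lymph nodes, had 278 and 1458 UMIs.

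Of the 21 gene lists fixed before the data were examined, the type 1 helper list was among those that differed most in the CD4 gate. Its 16 members had a median log2 ratio of 1.42 (1.20 to 1.61), 13 of them at least 1.5-fold higher and 0 at least 1.5-fold lower in Vaccine, above all 10000 random lists matched on expression (percentile 100). The type I interferon, interferon gamma, costimulatory and trafficking lists also reached percentile 100, so the percentile does not set this list apart. The median over all 9740 genes was itself 0.17 under scaling to total UMIs and 0.01 under median-of-ratios scaling, a shift of -0.16. Relative to the median over all genes, the type 1 helper list stood at 1.25. The naive and memory list had a median of -1.63 (-1.74 to -1.505), or -1.81 relative to all genes, with 10 of 12 members at least 1.5-fold lower and 0 higher. Type I interferon response genes had a median of 1.06 (0.78 to 1.33), or 0.89 relative to all genes, with 16 of 17 higher, led by the antiviral genes Rsad2 at 2.77 (1.72 to 4.03) and Mx1 at 2.38 (1.47 to 3.44). Interferon gamma response genes stood at 0.75 (0.60 to 0.98), with 15 of 21 higher, among them the transcription factor Irf8 at 2.09 (1.40 to 2.85) and the guanylate-binding protein gene Gbp6 at 1.83 (1.22 to 2.50). Costimulatory receptors stood at 0.78 (0.56 to 0.97), with 6 of 10 higher. Cd40lg, the helper ligand that licenses antigen-presenting cells, stood at 1.26 (1.10 to 1.43) and Cd226 at 1.32 (0.98 to 1.68), whereas Tnfrsf9 stood at -1.27 (-1.49 to -1.05). The cytokine and chemokine list went both ways, with a median of 0.94 (0.42 to 1.53), 6 of 11 members higher and 3 lower. Ccl3 at -3.41 (-4.13 to -2.77) and Ccl4 at -2.39 (-2.68 to -2.11), chemokines of cytotoxic and activated T cells, were lower in Vaccine, and Il2 at 1.65 (0.59 to 2.88) was higher. In the cytotoxic effector list, with a median of 0.52 (0.16 to 0.75), 7 of 15 members were higher and 3 lower. Ctsw, a cathepsin of cytotoxic cells, stood at 1.62 (1.47 to 1.78), and Gzma, granzyme A, at -2.15 (-2.39 to -1.91).

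Regulatory T genes as a list had a CD4 median of -0.61 (-1.11 to 0.05), or -0.79 relative to all genes, with 8 of 15 members lower and 1 higher. Gpr83 stood at -3.99 (-7.13 to -1.97) and Foxp3 at -1.35 (-2.004 to -0.72), whereas Nrp1 stood at 1.47 (1.06 to 1.91). Without the cells that held a Foxp3 UMI the list median was 0.18. The stem-like list stood at -0.94 (-1.45 to -0.46), with 7 of 12 members lower and 1 higher, and shared members such as Ccr7, Il7r, Tcf7, Lef1 and Bach2 with the naive and memory list. Exhaustion and checkpoint genes stood at -0.26 (-0.65 to 0.05), with 3 of 15 higher and 5 lower. Eomes stood at -2.73 (-4.49 to -1.31) and Cd200r4 at 1.82 (0.82 to 2.96). Trafficking receptors stood at 0.69 (0.46 to 0.94), with 8 of 14 higher and 2 lower. T cell receptor activation genes stood at 0.57 (-0.15 to 0.91), type 1 regulatory genes at 0.60 (-0.54 to 1.06), tissue residency genes at 0.32 (0.09 to 0.59), oxidative phosphorylation at 0.25 (0.12 to 0.35), and glycolysis and hypoxia at 0.21 (0.10 to 0.28). Proliferation genes at 0.06 (-0.37 to 0.65) and follicular helper genes at 0.04 (-0.56 to 0.24) lay below the median of all genes, at -0.11 and -0.14 relative to it. The dissociation stress list, genes induced by tissue digestion, stood at -0.23 (-0.43 to -0.15), with 5 of 16 members lower in Vaccine. Of the 8 type 2 helper genes 4 were measured, with a median of 1.72 (0.61 to 3.47), and of the 8 type 17 helper genes 2 were measured, at 0.52 (-0.10 to 1.16).

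The CD4 list differences depended on clone size. Among cells of clonotypes of 1 (793 Vaccine and 786 Control cells), the medians were 1.65 (1.38 to 1.88) for the type 1 helper list and -1.65 (-1.77 to -1.49) for the naive and memory list. Among cells of clonotypes of at least 2 (306 Vaccine and only 75 Control cells), they were -0.09 (-0.55 to 0.38) for the type 1 helper list, 0.22 (-0.19 to 0.76) for the naive and memory list, -0.93 for cytokines and chemokines, 0.11 for the stem-like list and -0.07 for costimulatory receptors. Assigning cells by cluster gave 2.17 for the type 1 helper list and -0.02 for the type 1 regulatory list, with most such Control cells in cluster 5 (1271) and most such Vaccine cells in cluster 1 (1768). Single genes turned as well. In clonotypes of at least 2, Ifng, the middle member that set the cytokine and chemokine median, stood at -0.93. Cd200r4 stood there at -0.53, Nrp1 at -0.08 and Tcf7 at 1.09. By cluster, Ccl3 stood at 0.34, Ccl4 at 1.16, Eomes at 0.89 and Ifit3 at -0.13.

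In the CD8 gate (5369 Vaccine and 4310 Control cells), the cytotoxic and the exhaustion and checkpoint lists were higher in Vaccine and the naive and memory list lower. The libraries also differed in their clusters with a CD8 majority: clusters 6, 11 and 14 held 785, 856 and 1350 Control and 0, 106 and 22 Vaccine cells, and clusters 9, 12 and 17 held 227, 323 and 97 Control and 1194, 1479 and 1495 Vaccine cells. Lag3 (ENSMUSG00000030124), an inhibitory receptor of activated T cells, stood at 142 CPM in Vaccine and 40.8 CPM in Control, a log2 ratio of 1.80 (1.69 to 1.91). Gzmb (ENSMUSG00000015437), the killing protease granzyme B, stood at 709 CPM (699 to 719) against 460 CPM (451 to 470). Ifng stood at 222 CPM (217 to 228) against 94.4 CPM (90.2 to 98.8). Ccr7 stood at 33.5 CPM in Vaccine and 284 CPM in Control, a log2 ratio of -3.08 (-3.18 to -2.98).

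After Lag3, genes among the highest CD8 ratios were the chemokine receptor Ccr2 at 1.75 (1.66 to 1.83), Rgs16 at 1.67 (1.498 to 1.84), S100a6 at 1.54 (1.51 to 1.57), Cxcr3 at 1.53 (1.46 to 1.59), the integrin chain Itgb1 at 1.45 (1.39 to 1.51) and S100a4 at 1.38 (1.33 to 1.43). Among the lowest, besides Ccr7, were Igfbp4 at -7.32 (-8.04 to -6.69), Rhob at -2.79 (-3.00 to -2.59), Dapl1 at -2.37 (-2.51 to -2.24), the heat shock gene Hspa1a at -2.08 (-2.24 to -1.92), Nsg2 at -2.07 (-2.24 to -1.90) and Tsc22d3 at -2.03 (-2.08 to -1.99). Tsc22d3 (ENSMUSG00000031431), a leucine zipper protein gene induced by glucocorticoids, and Rhob were also higher in Control than in the naive lymph node, 4.93-fold and 5.81-fold in the CD8 gate.

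The cytotoxic effector list had a CD8 median of 0.76 (0.67 to 0.87), with 12 of 18 members at least 1.5-fold higher and 0 lower, again above all matched random lists (percentile 100). Other lists reached percentile 100 as well, among them type 1 helper, exhaustion and checkpoint, proliferation and both interferon lists. The median over all 11579 genes was 0.18 in this gate and -0.01 under median-of-ratios scaling, a shift of -0.18, and the cytotoxic list stood at 0.59 relative to it. Among granzymes with few UMIs, Gzmd had 115 in Vaccine and 0 in Control (at least 27.6-fold higher against a floor of 3 UMIs), Gzme 44 and 0 (at least 10.5-fold) and Gzmf 51 and 1, a log2 ratio of 5.197 (2.65 to 10.53). Of the Gzmf UMIs in Vaccine, 7 lay in clonotypes of at least 2 and 44 in clonotypes of 1. Exhaustion and checkpoint genes stood at 0.64 (0.49 to 0.81), with 10 of 16 higher and 1 lower, including Nr4a2, a T cell receptor-induced nuclear receptor, at 1.28 (1.14 to 1.42). Type 1 helper genes stood at 0.84 (0.73 to 0.94) with 14 of 16 higher, and trafficking receptors at 0.91 (0.84 to 0.97) with 9 of 14 higher and 2 lower, Ccr7 among them. Interferon gamma response genes stood at 0.87 (0.75 to 0.94), with 14 of 21 higher, among them Irf8 at 1.53 (1.30 to 1.77) and Irgm1, an interferon-induced GTPase gene, at 1.18 (1.07 to 1.28). Type I interferon response genes stood at 0.66 (0.50 to 0.79), with 11 of 17 higher, led by Zbp1 at 1.15 (1.07 to 1.24) and Ifit1bl1 at 1.11 (0.96 to 1.27). Proliferation genes stood at 0.61 (0.35 to 0.89), with 12 of 24 higher and 0 lower, including Mki67 at 1.16 (0.79 to 1.54). Cytokines and chemokines stood at 0.64 (0.52 to 0.77), with 7 of 11 higher, led by Il2 at 2.24 (1.51 to 3.04), whereas Tnfsf8 stood at -2.15 (-2.42 to -1.89).

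The naive and memory list had a CD8 median of -1.09 (-1.23 to -1.02), or -1.27 relative to all genes, with 9 of 12 members lower and 0 higher. The stem-like list stood at -0.88 (-0.95 to -0.77), with 7 of 12 lower. Dissociation stress genes stood at -0.29 (-0.36 to -0.21), with 5 of 16 lower, led by Hspa1a, Hspa1b at -1.63 (-1.88 to -1.39) and Jun at -1.36 (-1.41 to -1.31). Costimulatory receptors stood at 0.72 (0.60 to 0.84), type 1 regulatory genes at 0.59 (0.19 to 0.94), T cell receptor activation at 0.41 (0.26 to 0.76), follicular helper genes at 0.38 (-0.23 to 0.75) and oxidative phosphorylation at 0.30 (0.24 to 0.36). Tissue residency at 0.14 (0.01 to 0.26), glycolysis and hypoxia at 0.12 (0.04 to 0.16) and regulatory T genes at -0.08 (-0.72 to 0.11) lay below the median of all genes, at -0.03, -0.06 and -0.26 relative to it. The type 2 and type 17 helper lists had 1 measured member each, at 0.60 (0.48 to 0.71) and 0.32 (0.24 to 0.41). Among CD8 cells of clonotypes of at least 2 (3179 Vaccine and 1475 Control cells), the medians were -0.04 (-0.10 to 0.03) for cytotoxic, 0.01 (-0.32 to 0.14) for naive and memory and 0.18 for stem-like genes, whereas interferon gamma response genes stood at 0.99. Among those of clonotypes of 1 (1851 and 2292 cells), they were 1.07 (0.93 to 1.14) for cytotoxic and -1.24 (-1.42 to -1.06) for naive and memory genes. In clonotypes of at least 2, Gzmb stood at -0.21, Havcr2 at -0.06 and Tnfsf8 at 0.12.

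**Figure D1:**
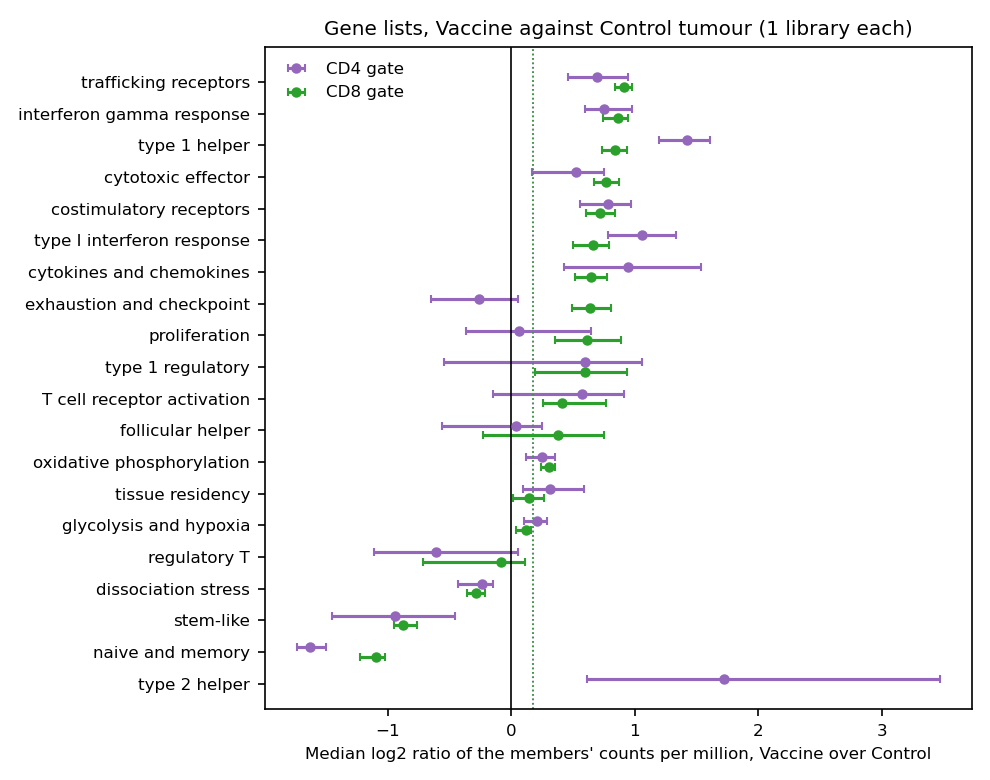
Median log2 ratio of CPM (x axis, Vaccine over Control) of each fixed gene list with at least 3 measured members (y axis), in the CD4 gate (purple) and the CD8 gate (green). Bars run between the medians of the members' lower and upper 95% counting limits. The solid line marks 0 and the dotted lines mark the median of all genes in each gate, 0.17 and 0.18. Naive and memory genes lie lowest among lists shown for both gates, at -1.63 and -1.09.

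**Figure D2:**
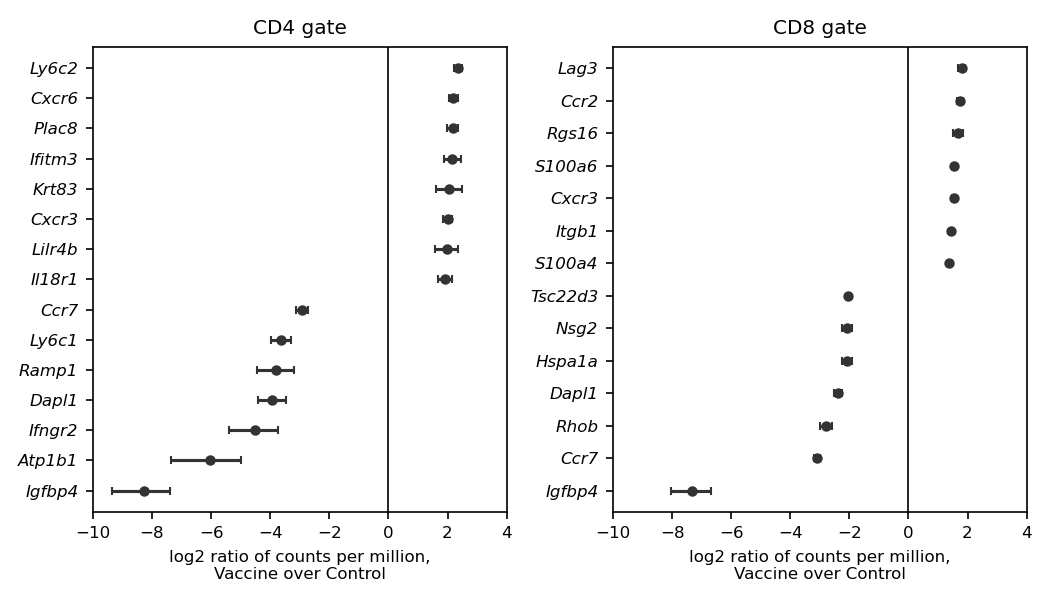
Log2 ratio of CPM (x axis, Vaccine over Control) of genes among the 8 highest and 8 lowest (y axis) of the CD4 gate (left) and the CD8 gate (right), 1 library per group. Bars are 95% counting intervals. Igfbp4 lies lowest in both gates, at -8.29 and -7.32.

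Shares of cells with a UMI of single markers, taken after thinning every cell to 1500 UMIs, showed the same split between naive and effector genes. In the CD4 gate, Ifng was present in 24.5% (22.0 to 27.1) of 1130 Vaccine cells and 6.58% (5.06 to 8.39) of 915 Control cells, and in 0 of 1423 naive lymph node cells, which allows up to 0.211% of cells with a UMI. Cxcr6 was present in 42.2%, 10.1% and 0.212% of Vaccine, Control and naive lymph node CD4 cells, Cd44, an activation marker, in 13.9%, 4.79% and 1.09%, Ccr7 in 6.61%, 34.9% and 50.1%, and Tcf7, a factor of naive and stem-like cells, in 24.2%, 35.7% and 45.4%. Gzmb was present in 6.95% of Vaccine and 6.71% of Control CD4 cells, a difference of 0.24 points (-2.07 to 2.48) that was not detectable, as was that of Pdcd1, the gene of the PD-1 receptor, at 8.26% and 7.35% (0.91 points, -1.53 to 3.29). In the CD8 gate, Gzmb was present in 35.0% (33.7 to 36.3) of 5197 Vaccine cells, 24.1% (22.8 to 25.4) of 4196 Control cells and 0.159% of 2051 naive lymph node cells. In the same order, Ifng was present in 23.6%, 11.8% and 0.0974% of CD8 cells, Cxcr6 in 48.6%, 23.9% and 7.66%, Pdcd1 in 17.8%, 14.1% and 0.207%, Havcr2, the TIM-3 receptor gene, in 1.47%, 0.829% and 0, and Ccr7 in 3.74%, 22.2% and 44.2%. Mki67 was present in 0.828%, 0.450% and 0.147% of CD8 cells, and Tox, a factor of exhausted cells, in 6.49%, 4.30% and 8.56%.

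Foxp3 was present in 0.676% (0.285 to 1.35) of Vaccine CD4 cells, 1.48% (0.7995 to 2.49) of Control and 0.813% (0.415 to 1.43) of naive lymph node CD4 cells after thinning. Vaccine minus Control was -0.80 points (-1.88 to 0.15), a difference not detectable at this depth, and -1.95 points without thinning (1.20%, 14 of 1171 cells, against 3.15%, 30 of 953). The summed UMIs gave a log2 ratio of -1.35 (-2.004 to -0.72), so the measures differ on whether Foxp3 was detectably lower. The regulatory T-like cluster 0, taken over all gates, held 71 of 7549 Vaccine and 188 of 6787 Control cells. In the CD8 gate, which should lack regulatory T cells, Foxp3 was present in 0.0940%, 0.231% and 0.390% of Vaccine, Control and naive lymph node cells. Median UMIs per cell were 4508, 3698 and 5083 in the CD4 gate and 4761, 4171.5 and 5891 in the CD8 gate.

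**Figure D3:**
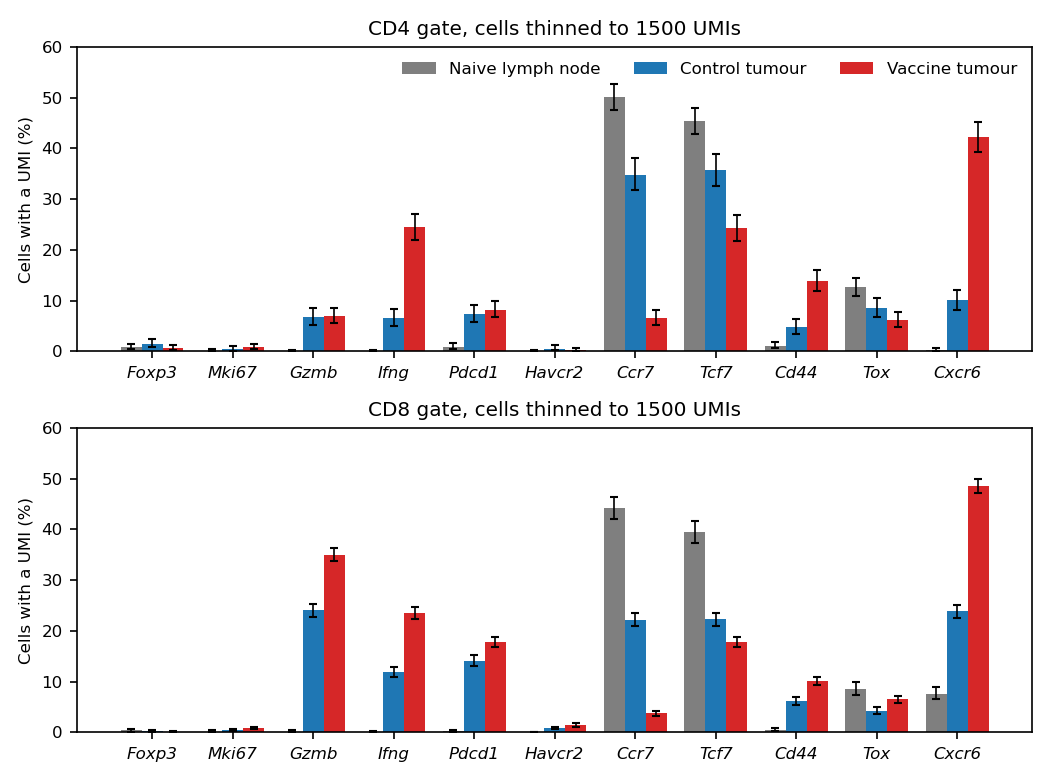
Percent of cells with at least 1 UMI (y axis) of fixed markers (x axis) in the CD4 gate (top) and CD8 gate (bottom), after thinning to 1500 UMIs, for the naive lymph node, Control and Vaccine libraries. Bars are shares and error bars are exact 95% binomial intervals over cells. Cxcr6 stands at 42.2% and 48.6% in the Vaccine library and at 10.1% and 23.9% in Control.

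Control tumours against the naive lymph node showed effector genes that were nearly absent from the lymph node and interferon-stimulated genes that were lower in the tumour. In the CD4 gate, Ccl4, Gzmb, Gzmk and Ifng had 493, 506, 237 and 335 UMIs in Control and 0 in the 1443 naive lymph node cells, at least 337-fold, 346-fold, 162-fold and 229-fold higher against a floor of 3 UMIs. Lgals3, galectin-3, had 271 and 2 UMIs, a log2 ratio of 8.12 (6.25 to 11.17), and Ccl5, a chemokine of effector and memory T cells, had 7205 and 66, a ratio of 7.81 (7.46 to 8.18). The lowest genes were the interferon-induced Ifit3 at -3.65 (-4.08 to -3.24), Ifit3b at -3.48 (-3.95 to -3.05), Isg15 at -3.12 (-3.33 to -2.91), Oasl2 at -2.78 (-3.22 to -2.37), Slfn5 at -2.66 (-3.05 to -2.30) and Rnf213 at -2.64 (-2.96 to -2.34). In the CD8 gate, Ccl3, Gzmk, Ifitm1, Klrk1 and S100a4 had 1239, 4260, 5258, 3480 and 3794 UMIs in Control and 0 in the naive lymph node, at least 264-fold, 908-fold, 1120.4-fold, 742-fold and 808-fold higher. Klrk1 encodes the activating receptor NKG2D. Lgals3 had 6449 and 1 UMIs, a log2 ratio of 12.01 (9.53 to 17.31). The lowest CD8 genes were Oasl2 at -3.51 (-3.75 to -3.27), Art2b at -3.18 (-3.42 to -2.95), the gut-homing receptor Ccr9 at -3.15 (-3.37 to -2.94), Isg15 at -3.12 (-3.21 to -3.03), Ifi27l2a at -2.90 (-2.94 to -2.86) and Slfn5 at -2.74 (-2.96 to -2.53).

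By list, type 1 helper genes were higher in Control in 16 of 16 CD4 members (median 5.23, 3.82 to 6.44), cytotoxic genes in 13 of 14 measured CD8 members (4.04, 3.60 to 4.52) and exhaustion and checkpoint genes in 13 of 16 CD8 members (2.96, 2.34 to 3.35), including Tigit at 7.41 (6.75 to 8.17) and Pdcd1 at 6.44 (5.77 to 7.20). Regulatory T genes were higher in 11 of 15 CD4 members (1.72, 1.55 to 2.23), with Ccr8 at 2.57 (1.9575 to 3.22). Type I interferon response genes were lower in 17 of 18 members in both gates, with medians of -2.30 (-2.57 to -2.03) for CD4 and -2.05 (-2.18 to -1.93) for CD8. The interferon gamma list stood at -0.11 (-0.29 to 0.12) in CD4 cells and -0.28 (-0.38 to -0.16) in CD8 cells, with 6 of 21 CD8 members lower and 1 higher. Naive and memory genes stood at -0.42 (-0.53 to -0.28) in CD4 and -0.66 (-0.78 to -0.58) in CD8 cells. Dissociation stress genes were higher in 14 of 15 CD4 members (1.48, 1.39 to 1.56) and 15 of 16 CD8 members (1.30, 1.19 to 1.41), with Hspa1a at 303 UMIs against 3 in CD4 cells, a log2 ratio of 7.69 (6.13 to 9.98). The protocol in the labels describes digestion of tumours and none of lymph nodes. Against the same lymph node library, Vaccine CD4 cells had medians of 6.47 (5.07 to 7.85) for type 1 helper genes, -1.84 (-1.93 to -1.66) for naive and memory genes and -1.34 (-1.54 to -1.14) for type I interferon response genes, and Vaccine CD8 cells had 3.98 (3.17 to 4.58) for exhaustion and checkpoint genes and 1.05 (0.96 to 1.13) for dissociation stress genes.

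Clonal expansion, read from the receptor libraries, was almost nil in the naive lymph node, present in Control and widest in Vaccine. Cells in clonotypes of at least 2 cells made up 0.288% (0.158 to 0.483) of naive lymph node cells, 28.3% (27.1 to 29.5) of Control and 52.9% (51.7 to 54.1) of Vaccine. Vaccine exceeded Control by 24.6 points (23.0 to 26.3) and Control exceeded the naive lymph node by 28.0 points (26.8 to 29.2). Clonotypes of at least 5 cells held 0, 17.9% (16.97 to 19.0) and 32.6% (31.5 to 33.7) of cells, the count of 0 of 4860 allowing up to 0.0617%, a difference between Vaccine and Control of 14.7 points (13.2 to 16.1). The 10 largest clonotypes held 0.350%, 8.29% and 12.3% of cells, and Shannon clonality was 6.54e-05, 0.0472 and 0.0837. Rarefied to 4860 cells, expanded clonotypes held 27.3% of Control and 48.9% of Vaccine cells. Both chains were found in 84.6%, 77.8% and 89.1% of cells with a productive chain. Among the 10 largest clonotypes, ranks 3, 6, 7 and 8 of Control lacked a chain, and none of Vaccine did. With clonotypes by beta chain nucleotides, the 10 largest held 11.85% of Control and 15.01% of Vaccine cells with a beta chain. Clonotypes of at least 5 cells then held 23.1% and 42.1%. Unequal splitting of clones may thus add to the gap in the 10 largest clonotypes. It did not do so for clonotypes of at least 2 or 5 cells. By beta chain nucleotides Vaccine exceeded Control by 31.3 points at clonotypes of at least 2.

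By gate, cells in clonotypes of at least 2 were 8.71% (6.91 to 10.8) of 861 Control and 27.8% (25.2 to 30.6) of 1099 Vaccine CD4 cells, and 39.2% (37.6 to 40.7) of 3767 Control and 63.2% (61.9 to 64.5) of 5030 Vaccine CD8 cells. Vaccine exceeded Control by 19.1 points (15.8 to 22.4) in the CD4 gate and 24.0 points (22.0 to 26.1) in the CD8 gate. The largest CD4 clonotypes held 7 cells in Control and 10 in Vaccine, and the largest CD8 clonotypes 145 and 189. Clonotypes of at least 5 cells held 3.14% (2.08 to 4.53) of Control and 3.64% (2.61 to 4.92) of Vaccine CD4 cells, and 26.0% (24.6 to 27.4) and 43.4% (42.1 to 44.8) of CD8 cells. In the naive lymph node, 0.286% of 1400 CD4 and 0.101% of 1983 CD8 cells were expanded. With clone size counted within the CD4 gate, Vaccine exceeded Control by 15.2 points there, and by 12.2 with equal numbers of cells as well, and with cells assigned by cluster Control exceeded the naive lymph node by 3.88 points in place of 8.43. Clonotypes with cells in both gates were rare, 5 of 278 in Control and 9 of 628 in Vaccine among clonotypes with at least 2 gated cells.

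**Figure D4:**
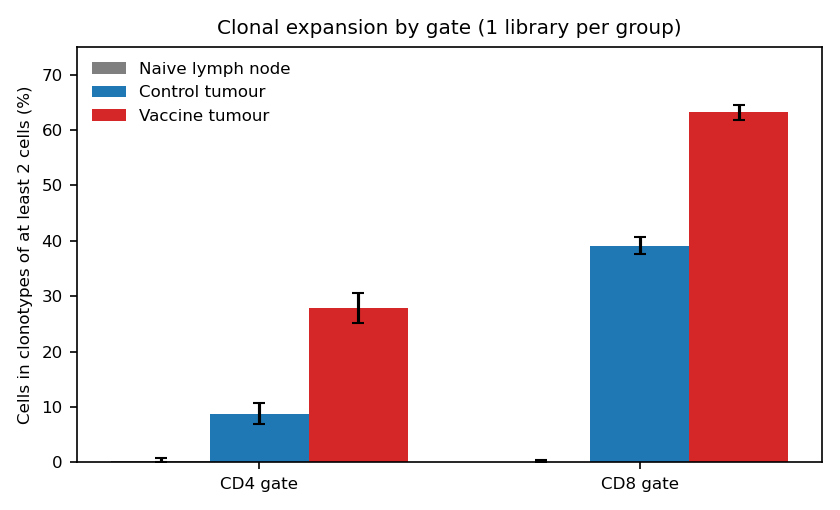
Percent of cells in clonotypes of at least 2 cells (y axis) in the CD4 and CD8 gates (x axis) of the naive lymph node, Control and Vaccine libraries. Error bars are exact 95% binomial intervals over cells. The Vaccine library stands at 27.8% and 63.2%, Control at 8.71% and 39.2%.

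The largest expanded clonotypes were CD8 cells. In Control, the largest held 145 cells (2.48%), all in the CD8 gate, and paired the TRAV6-2 alpha chain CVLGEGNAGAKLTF with the TRBV14 beta chain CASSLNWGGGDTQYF. In Vaccine, the largest held 190 cells (2.71%), 189 of them in the CD8 gate, and paired the TRAV9-1 alpha chain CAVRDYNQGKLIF with the TRBV2 beta chain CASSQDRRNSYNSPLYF. The clonotypes of rank 2, 3 and 7 in Vaccine, with 109, 96 and 75 cells, shared the TRBV5 beta chain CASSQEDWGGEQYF and had TRAV13-1 and TRAJ34 alpha chains, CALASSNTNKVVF, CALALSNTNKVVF and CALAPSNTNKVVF. TRBV5 was carried by 10.8% of Vaccine cells with a beta chain and 5.03% of Control cells, but by 6.95% and 5.19% of clonotypes counted once each. TRBV13-1 was carried by 11.1% and 6.598% of cells and 7.91% and 6.25% of clonotypes, and TRBV14 by 2.32% and 5.76% of cells and 3.14% and 3.02% of clonotypes.

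Few receptors were found in more than 1 library. Of 3257 paired amino acid sequences in Vaccine and 3436 in Control, 21 occurred in both, 5 of them expanded in both, whereas Control and the naive lymph node shared 0 and Vaccine and the naive lymph node shared 1. Beta chain amino acid sequences were shared more often, 161 between Vaccine and Control, 152 between Control and the naive lymph node and 91 between Vaccine and the naive lymph node. At the nucleotide level the paired count between Vaccine and Control was 5 and the beta chain counts were 36, 12 and 10. The pair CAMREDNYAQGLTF and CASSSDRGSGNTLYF was the most frequent shared one in Control, with 115 cells there and 9 in Vaccine, and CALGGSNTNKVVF with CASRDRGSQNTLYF was found in 14 Control and 32 Vaccine cells, both encoded by different nucleotides in the libraries.

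Cells of large clonotypes (at least 5 cells) differed from cells of single-cell clonotypes within each tumour. In Control (980 expanded and 2292 single CD8 cells), the highest genes in expanded cells were the interferon-induced Ifitm1 at a log2 ratio of 3.31 (3.21 to 3.42) and Ifitm2 at 3.15 (2.91 to 3.39), then Lgals3 at 2.81 (2.72 to 2.90), Ccr2 at 2.58 (2.38 to 2.77), Cx3cr1, a receptor of terminal effector cells, at 2.54 (2.28 to 2.80) and S100a4 at 2.43 (2.32 to 2.55). Among the lowest were Tmem108 at -8.01 (-13.32 to -5.53; 1 UMI against 858), Igfbp4 at -7.03 (-8.66 to -5.81), Ccr7 at -4.53 (-4.90 to -4.18), Dapl1 at -4.26 (-4.83 to -3.74) and Nsg2 at -3.65 (-4.30 to -3.07). In Vaccine (2185 and 1851 CD8 cells), the highest genes in expanded cells were the chemokine Ccl3 at 1.52 (1.38 to 1.67), Lag3 at 1.46 (1.35 to 1.57), Pdcd1 at 1.45 (1.35 to 1.55), Rgs16 at 1.34 (1.16 to 1.53), Lgals3 at 1.30 (1.23 to 1.37) and Tox at 1.21 (1.03 to 1.39). Among the lowest were Ccr7 at -2.45 (-2.74 to -2.17), the chromatin organiser Satb1 at -1.74 (-1.90 to -1.58), Fam46c at -1.14 (-1.36 to -0.93), the survival gene Bcl2 at -0.91 (-1.06 to -0.77) and Ms4a4c at -0.85 (-1.04 to -0.66).

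In the CD4 gate the large clonotypes held only 27 Control cells of 6 clonotypes and 40 Vaccine cells of 10 clonotypes. In Control they were higher for Nr4a2 at 4.96 (4.39 to 5.54), Gzmk at 4.88 (4.48 to 5.28), Rgs16 at 4.54 (4.11 to 4.98), Slamf7 at 4.54 (3.80 to 5.27), Ccl3 at 4.33 (3.83 to 4.82) and Il1r2 at 4.29 (3.44 to 5.12). Tgtp1, Tgtp2, Rab3ip, Traf4 and Psmd12 had 0 UMIs in these 27 cells, at least 4.88-fold, 4.27-fold, 3.04-fold, 2.28-fold and 2.12-fold lower than in single-cell clonotypes. In Vaccine they were higher for Ifitm1 at 3.01 (2.66 to 3.36), Adam8 at 2.23 (1.19 to 3.16), Ccl4 at 2.09 (1.14 to 2.93), F2rl2 at 2.03 (0.88 to 3.03), Sfn at 1.92 (0.78 to 2.91) and Tprn at 1.81 (0.68 to 2.79). They were lower for Ms4a4c and Hspa1a, both with 0 UMIs (at least 3.9995-fold and 4.38-fold), and for Izumo1r at -3.45 (-8.76 to -0.95), Cdc5l at -2.55 (-5.60 to -0.68), Crbn at -2.23 (-4.51 to -0.67) and Tspan32 at -2.07 (-4.36 to -0.51). In the 40 Vaccine cells, Adam8, Ccl4, F2rl2, Sfn and Tprn rested on only 12, 14, 10, 10 and 10 UMIs. Their CPM was 52.6 to 73.6 there and 12.9 to 17.4 in single-cell clonotypes. Only the CPM in expanded cells reached the minimum for naming genes, so being higher there was a condition of being named. That held for the genes named as higher in Control too. The intervals do not cover this selection or differences among clonotypes. Without the largest CD4 clonotype of Vaccine, Ifitm1 stood at -3.19, and at a minimum of 10 cells per clonotype Ccl4 stood at -0.25.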

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

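Of the tests in this part, 3 were chosen only after the result was seen: the stress of digestion for the genes high in Control, and the other sex and free RNA for Xist. The comparison within clonotypes of at least 2 cells was added once the data had been seen, with its outcome still unknown.

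Naive and memory genes were lower and effector genes higher in the Vaccine than in the Control library. The scale set by the ribosomal share of UMIs was argued against, since the cytotoxic list in CD8 cells kept a median log2 ratio of 0.58 (0.49 to 0.69) under median-of-ratios scaling. Among cells of clonotypes of at least 2, the medians were -0.042 (-0.10 to 0.026) for the cytotoxic list in CD8 cells and -0.093 (-0.55 to 0.38) for the type 1 helper list in CD4 cells. These values are consistent with a smaller share of unexpanded, naive-like cells in Vaccine as a source of the pattern, but expanded cells may by selection include few naive cells in either library, and among cells of clonotypes of 1 the difference was present, at 1.07 (0.93 to 1.14) and 1.65 (1.38 to 1.88), so a change within unexpanded cells stays open. Vaccination and any difference in how the tumours were sampled remain open, as neither was tested and both coincide with the library.

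Rhob, Tsc22d3, Bbc3 and Txnip were at least 2-fold higher in the Control library than in both others, in both gates, with a median log2 ratio of Vaccine over Control of -2.01 (-2.09 to -1.92) in CD8 cells; the same rule gave 22 genes for the naive lymph node and 22 for Vaccine. These genes were picked by this difference in the same cells, so its size was partly set by the rule. The 2 subsets below hold cells that the rule used. In clonotypes of at least 2 the median was -1.84 (-2.08 to -1.61), so expanded cells differed too. This cannot decide on more naive-like cells in Control, because the rule took only genes lower in the naive lymph node. Among cells with at least 4000 UMIs and at most 3% mitochondrial UMIs (2244 Control and 3328 Vaccine CD8 cells) the median was -1.92 (-2.03 to -1.82). The difference was thus not confined to damaged cells with little RNA, though the cells of this subset helped to pick the genes. Stress of digestion cannot be told apart from other explanations. The dissociation stress list stood at -0.29 (-0.36 to -0.21) with members going both ways, by counting intervals above 0 for 4 members and below 0 for 11, without the 1.5-fold rule. Its members Hspa1a, Hspa1b and Jun stood at -2.08, -1.63 and -1.36, and cluster 18 (115 of 117 cells from Control) was led by Hspa1a, Hspa1b, Dnajb1 and Rhob. A treatment effect and a handling difference between the tumour libraries stay open and were not tested.

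A signal outside the planned measurements was Xist, a transcript of female cells, with an Xist UMI in 7.06% (6.46 to 7.69) of Control cells, 1 UMI in the naive lymph node and 0 of 7549 Vaccine cells, which allows up to 0.0397% of cells with a UMI. Control cells with an Xist UMI held a Y-linked UMI 0.159 (0.107 to 0.228) times as often as those without one (6.68% of 479 against 42.0% of 6308), which is consistent with cells of a female animal among cells of male animals. Free RNA was argued against by the same counts, since cells with a Y-linked UMI held Xist 0.110 (0.0689 to 0.169) times as often as cells without one. This ratio reads the same cross-count of Control cells the other way, so it is not a separate test. Separate clones in the 2 groups of cells cannot be told apart from shared ones, at a ratio of 0.277 (0.0729 to 0.689) that rests on 34 cells. Xist UMIs were in 9.02% of Control cells in clonotypes of 1, 6.98% in those of 2 to 4 and 1.62% in those of 5 or more, and Xist was a top gene of cluster 11 (856 of 966 cells from Control), so a link with unexpanded cells stays open; no explanation from the groups of the design was tested, and the labels give no sex.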

How the results depend on the processing

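The alternatives without cells with more than 1 TRB chain, without the highest doublet scores, without cells with an Xist UMI, with cells of clonotypes of at least 2 only, and with clone size counted within the gate were tests chosen only after the data were seen. No paired analysis was possible because each group had 1 sample per assay. Where nothing else is said, the cause was not tested.

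Sign changes were counted only where the main value of a list or gene was at least 1.5-fold, or the interval of a marker share excluded 0. Values that moved outside their range may therefore include further sign changes. Apart from the main lists (naive and memory in both gates, CD4 type 1 helper, CD8 cytotoxic), 1128 list medians were recomputed: 1018 stayed within their range, 104 moved outside it and 6 were counted as sign changes. For named genes these counts were 1368, 242 and 15 of 1625, for marker shares 143, 33 and 0 of 176, for expanded against single cells 71, 59 and 2 of 132, for the repertoire 10, 6 and 0 of 16 and for sharing 1, 5 and 0 of 6.

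Among cells of clonotypes of at least 2, Vaccine over Control log2 values changed sign in the CD4 gate for the lists of naive and memory (0.22), type 1 helper (-0.093), cytokine and chemokine (-0.93), stem-like (0.11) and costimulatory genes (-0.071), and for Cd200r4 (-0.53), Ifng (-0.93), Il2 (-0.68), Nrp1 (-0.076) and Tcf7 (1.09). In the CD8 gate they changed sign for the naive and memory (0.014), cytotoxic (-0.042) and stem-like (0.18) lists and for Gzmb (-0.21), Gzmf (-0.25), Havcr2 (-0.058) and Tnfsf8 (0.12). Il2 (CD4 gate) and Gzmf (CD8 gate) had 9 and 7 UMIs in Vaccine and 0 in Control, so that their signs came from the floor of 3 UMIs put in for the 0 in the smaller Control total. In the CD4 gate the cytokine and chemokine median was the value of Ifng, its middle member.

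With the gate by cluster, the CD4 lists stood at -1.80 for naive and memory, 2.17 for type 1 helper and -0.018 for type 1 regulatory genes. Signs turned for Ccl3 (0.34), Ccl4 (1.16), Eomes (0.89) and Ifit3 (-0.13) in the CD4 gate and Foxp3 (1.20) in the CD8 gate. The CD8 share of gated cells differed by 4.81 points between Vaccine and Control and 30.2 between Control and the naive lymph node, and expanded CD4 cells by 22.5 and 3.88 points. With at least 2 UMIs for a gate, the CD8 share differed by -2.56 and 15.1 points, the CD4 type 1 helper list stood at 1.07, and Control exceeded the naive lymph node in expanded cells by 11.003 points (CD4) and 40.7 points (CD8). Thinning to 1500 or 1000 UMIs before the gate gave 14.1 and 11.4 points for the CD8 share of Control over the naive lymph node. Without thinning, the Foxp3 share differed by -1.95 points. Without cells with a Foxp3 UMI the CD4 regulatory T list stood at 0.18, since its Foxp3-positive cells were removed.

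Scaling moved the naive and memory list to -1.80 (CD4) and -1.28 (CD8) and the CD8 cytotoxic list to 0.58 under median-of-ratios, and to -1.79, -1.33 and 0.53 with totals without receptor, ribosomal and mitochondrial genes. With the mean of cells' CPM, the CD8 lists stood at -1.01 and 0.58.

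For cells in clonotypes of at least 2, Vaccine minus Control and Control minus naive lymph node were 31.3 and 32.2 points with clonotypes by TRB nucleotides, 29.1 and 31.0 with 1 TRA and 1 TRB chain, 26.3 and 29.3 without cells of more than 1 TRB chain, 19.0 and 23.2 at clonotypes of at least 3, and 14.7 and 17.9 at 5. Vaccine minus Control was 21.6 points when rarefied. By TRB nucleotides the gates gave 24.3 (CD4) and 29.2 (CD8) for Vaccine minus Control and 44.6 (CD8) for Control minus naive lymph node. With clone size counted within the gate, Vaccine minus Control and Control minus naive lymph node were 15.2 and 5.92 (CD4) and 24.0 and 38.7 (CD8). With equal numbers of gated cells on top of this they were 12.2 and 5.92 (CD4) and 18.5 and 34.6 (CD8). For CD8 cells, Control minus naive lymph node was 41.2 points without cells of more than 1 TRB chain and 40.7 without cells with an Xist UMI. Among expanded Vaccine CD4 cells, Ifitm1 stood at -3.19 without the largest clonotype and Ccl4 at -0.25 at clonotypes of at least 10 cells.

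Depth limited the shares of Foxp3, Havcr2 and Mki67, which lay between 0 and 1.48% of cells after thinning, and the CD4 expanded cells, 27 in Control and 40 in Vaccine.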

Other observations

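In this part, 0 tests were chosen only after the result was seen. In the Vaccine library 308 cells carried the beta chain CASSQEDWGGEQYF, and 119, 98 and 77 of them paired it with the TRAV13-1 and TRAJ34 alpha chains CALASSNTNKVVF, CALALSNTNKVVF and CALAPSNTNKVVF. The beta chain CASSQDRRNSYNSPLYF, in 277 Vaccine cells and 0 Control cells, had 9 nucleotide forms and paired mainly with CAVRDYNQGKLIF (195 cells), but also with alpha chains of TRAV7 segments such as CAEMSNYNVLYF (23 cells) and CAVRDYSNNRLTL (18 cells). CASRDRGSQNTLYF was found in 161 Vaccine and 17 Control cells.

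Several nucleotide sequences for 1 beta chain may point to selection of the same receptor in separate cells. Among 3000 beta chain clonotypes drawn per library, the median number of such chains over 1000 draws was 74 (65 to 80, lowest and highest draw) in Vaccine, 22 (13 to 30) in Control and 11 (4 to 18) in the naive lymph node. Sequencing errors in large clones may add to these numbers, which was not tested directly. Over all 3205, 3881 and 4705 beta chain clonotypes, chains whose forms differed at 2 or more positions numbered 47, 21 and 9. With each form also required in at least 2 cells, they numbered 9, 2 and 0, so most of these chains rested on a form seen in 1 cell.

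Against the naive lymph node, proliferation genes had a median log2 ratio of 1.40 (0.90 to 1.79) in Vaccine CD8 cells and 0.74 (0.26 to 1.22) in Control CD8 cells. Type I interferon response genes stood at -1.60 (-1.71 to -1.44) in Vaccine CD8 cells.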
